A study of Mus musculus with 6 samples.

How the data were processed

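Poly(A) RNA was sequenced from bone-marrow-derived macrophages of wild-type C57BL mice, cells grown from marrow precursors in culture. There were 2 groups of 3 libraries. Untreated macrophages formed the first group. The second group had been kept for 24 hr with thymocytes driven into apoptosis with dexamethasone, a synthetic glucocorticoid, at a ratio given as 1:40, and the apoptotic cells were taken off before RNA was extracted. The series' design text states that the samples are biological replicates. Libraries were strand-specific TruSeq mRNA libraries read on a NextSeq instrument, per the labels' protocols.

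The deposited values were RPKM (reads scaled by gene length in kilobases and by the mapped reads of the library), per the file headers, for 38124 genes with 1 column per library. Annotation was on mouse GRCm38 (mm10), per the labels and the submitters' processing notes. The aligner, the counting program, the gene model release, the use of strand and the treatment of reads that match several genes were not given in the sources used here. For this reason, values of genes with near-identical copies or processed pseudogenes, of overlapping genes and of antisense genes are uncertain. Each table column matched the title of 1 sample, and 0 columns belonged to no sample. Coordinates are those of the deposited table, 1-based, on mm10. Gene symbols were used as the table gives them. GENCODE M21 identifiers matched 36345 of the 38124 rows.

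Reads behind the values were recovered as follows. RPKM times gene length times depth is the number of reads, so the depth of each library and the length of each gene were searched for the values that make all 6 read numbers whole. All 18737 genes above 0 in any library came out whole within 0.001 reads, 9371 of them with the union exon length of GENCODE M21 and 9366 with a length found by the search, up to 30000 bp. On simulated reads for 17708 genes the procedure returned the exact depth of all 6 libraries and the exact reads of 97.3% of genes, and the rest differed by a common factor within the gene. The recovered depth was 19315132, 23907256 and 23070545 mapped reads in untreated replicates 1 to 3, and 25933208, 22782450 and 23551544 in treated replicates 1 to 3. At these depths 1 read on a gene of 1 kb was worth 0.0386 to 0.0518 RPKM. PCR duplicates cannot be recognised in these values, so intervals from reads cover counting error only.

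A count model had been fixed as the first choice for the gene test, with limma on log values as the fallback for a normalised unit. Because the deposited values were RPKM and not counts, the fallback was used. Genes at 1 RPKM or more in at least 3 libraries were kept, and log2(RPKM + 1) was fitted in limma 3.58.1 (R 4.3.3) with an intensity trend and the group as the only term. P values were adjusted by the Benjamini-Hochberg method, and a gene counted as changed at an adjusted p under 0.05. Log2 changes are treated minus untreated on the log2(RPKM + 1) scale, which understates the change of genes near 1 RPKM, and SE is the moderated standard error of that change. Folds are ratios of mean RPKM. The tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

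Gene lists were fixed before the data were examined. There were 28 lists with 433 entries, all found in the table, 9 of them under an older or newer symbol, and 334 entries passed the expression filter. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, which compares the members with all other tested genes, and p was adjusted over the 22 lists tested. The same test with an estimated correlation and fry, which asks whether members move on balance in 1 direction without comparing them with other genes, were run beside it. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the number of tested genes. This gives a larger p for the same statistic. List means and medians are given relative to the median tested gene. The genes named in the text were also fixed by rule. They are the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 RPKM, group ranges that do not overlap and a symbol that is not a predicted or clone-based name or a numbered duplicate, every measured member of the pentose phosphate pathway list, up to 3 members of every other list with the smallest p, and for cell type lists also up to 3 members with the highest treated mean. Of the genes picked by this rule, 2 are not reported here. Members named as the exceptions within a list or as too low to be tested, and Gapdh, were chosen after their values were seen.

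The gene test was tested on reads simulated from the means of the untreated libraries and the depths of all 6, with 200 genes changed before the expression filter. After the filter 10040 genes were tested, with 49 or 50 changed genes at each fold. The test called 84% of genes changed 1.25-fold in the right direction and 100% of those changed 1.5-fold, 2-fold or 4-fold, and it called 8 of 9841 unchanged genes. Every simulated library had 1 dispersion for all genes, 0.000176, the median of values per gene from the untreated libraries. Differences in spread between genes were left out, so real untreated libraries can vary more than the simulated ones. Real treated libraries differed more than untreated ones, with a chi-square per gene of 5.27 to 18.7 between pairs against 1.74 to 3.48 among untreated. Far more genes, 6594, were called in the data, so these rates do not carry over to them. The set test gave an unadjusted p under 0.05 for 3 of 200 random lists of 15 unchanged genes. Simulated genes were drawn independently, so this check does not cover correlation among the members of a list. Estimated correlations of the fixed lists ran from -0.0456 to 0.688.

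Alternatives were median-of-ratios scaling, upper-quartile scaling, limma-voom on the recovered reads, no filter on low values, a filter at 5 RPKM, a pseudocount of 0.1, the replicate number as a block, leaving out each library in turn, stricter thresholds, and the estimated correlation in the set test. For the fits that leave out a library, the gene set of the full fit was kept, a choice made after a filter reapplied to 5 libraries had dropped genes expressed in only 1 group. Other data of the study were not analysed here.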

Results

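RNA of cultured mouse bone-marrow-derived macrophages was profiled with and without 24 hr of exposure to apoptotic thymocytes, in 3 untreated and 3 treated libraries. Exposure to apoptotic cells loads macrophages with their remains, a process called efferocytosis, and the title of the series names the pentose phosphate pathway in its stress. Depth was 19315132 to 25933208 mapped reads per library, of which 17489692 to 23692222 fell on genes. Libraries of 1 group were close to each other, with Pearson r across genes of 0.994 to 0.998, while r between groups was 0.935 to 0.940. The first principal component held 93.1% of the variance and separated the groups. Within each group every pair of libraries differed by more than counting noise, with a chi-square per gene of 1.74 to 3.48 among untreated and 5.27 to 18.7 among treated libraries, so 0 pairs were treated as the same library deposited again. The highest value lay between treated replicates 1 and 3.

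Of 10173 tested genes, 1915 were higher and 4679 lower with apoptotic thymocytes (limma on log2(RPKM + 1), adjusted p under 0.05), a total of 6594 or 64.8%. The groups' ranges did not overlap in 69.6% of tested genes, against 10% by chance. The split into higher and lower genes moved with the scaling. The median tested gene had a log2 change of -0.13, and with median-of-ratios scaling, which puts the median near 0, 3064 genes were higher and 3023 lower. Of the 1915 higher calls 0 were lost under that scaling, whereas 1656 of the 4679 lower calls were, 31 of them because the gene fell below the expression filter after scaling, and 0 calls changed direction. That scaling divides untreated libraries by 1.05 to 1.06 and treated libraries by 0.948 to 0.955, which moves changes upward. Higher calls could therefore hardly be lost, and that they were kept is no evidence for them. Larger changes are subject to the same shift. At a log2 change beyond 1, 250 genes were higher and 574 lower, of which 250 and 467 stayed beyond 1 after scaling. The 20 most abundant genes took 15.7% ± 0.0604 of gene reads in untreated and 21.9% ± 0.580 in treated libraries (mean ± SD, n = 3).

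On the log2(RPKM + 1) scale, the largest rises were led by Chi3l3, Gsta3, Hmox1, Ddit4 and Saa3. Values here and in the following are mean RPKM ± SD of 3 libraries. Chi3l3 (current symbol Chil3, ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), a chitinase-like secreted protein, rose from 0.489 ± 0.188 to 57.5 ± 0.414 (log2 change 5.30, SE 0.0837, adjusted p = 1.93e-10). Gsta3 (chromosome 1, 21240589 to 21265361), a glutathione S-transferase, rose from 1.43 ± 0.360 to 92.3 ± 3.70 (log2 change 5.27, SE 0.0938). Hmox1 (chromosome 8, 75093591 to 75100596), the heme-degrading enzyme heme oxygenase 1, rose 37.0-fold from an already high level, 144 ± 2.36 to 5322 ± 165 (log2 change 5.20, SE 0.0480). Ddit4 (chromosome 10, 59949675 to 59951770), an inhibitor of mTORC1 signalling, rose from 0.698 ± 0.128 to 61.3 ± 5.07. Saa3 (chromosome 7, 46711998 to 46715676), an acute-phase serum amyloid protein, rose from 5.43 ± 0.981 to 186 ± 31.5, with the largest SE of the 10 (0.136). The scavenger receptor gene Marco rose from 1.02 ± 0.0736 to 50.1 ± 3.14, the glucocorticoid-induced co-chaperone gene Fkbp5 from 2.0 ± 0.134 to 73.2 ± 2.90, and Clec4n, which encodes Dectin-2, from 26.6 ± 0.320 to 479 ± 15. Bst1, an ADP-ribosyl cyclase gene, rose from 0.633 ± 0.0612 to 29.1 ± 1.38. Amica1 (current symbol Jaml), an adhesion molecule gene, stood at 0.0349 ± 0.0353 in untreated libraries, where 1 library was at 0, and at 18.2 ± 0.204 in treated libraries. Its ratio of means, 523, was the highest of the 10 but rests on an untreated level near 0. Chi3l3, Gsta3 and Saa3 have close paralogs, and reads shared with these could have been split or counted in more than 1 gene.

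The largest falls were led by Plau, Pcp4l1, Ccnd1, Kcnn4 and Pdgfb. Plau (ENSMUSG00000021822, chromosome 14, 20836662 to 20843388), the urokinase-type plasminogen activator, fell from 135 ± 7.66 to 2.87 ± 0.278 (log2 change -5.13, SE 0.0639, adjusted p = 7.16e-11). Pcp4l1 (chromosome 1, 171173262 to 171196268) fell from 83.7 ± 4.12 to 2.93 ± 0.360. Ccnd1 (chromosome 7, 144929931 to 144939869), which encodes cyclin D1, fell 29.3-fold from 41.6 ± 2.10 to 1.42 ± 0.0628. Kcnn4 (chromosome 7, 24370263 to 24385209), a calcium-activated potassium channel gene, fell from 78.2 ± 3.10 to 4.09 ± 0.272. Pdgfb (chromosome 15, 79995900 to 80014808), a growth factor gene, fell from 26.7 ± 0.914 to 0.875 ± 0.0810. Tnip3, whose product restrains NF-kB signalling, fell from 19.4 ± 1.27 to 0.402 ± 0.0511, Pcdh7 from 21.8 ± 1.11 to 0.603 ± 0.0646 and Nptx1 from 15.8 ± 0.417 to 0.217 ± 0.0470. The MHC class II gene H2-Eb1 fell from 78.1 ± 1.23 to 4.87 ± 0.406, and the inhibitory lectin receptor gene Clec12a from 84.5 ± 2.71 to 5.59 ± 0.224. The 20 genes, which were picked for large changes, kept their direction and their call under every alternative run for single genes.

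**Figure D1:**
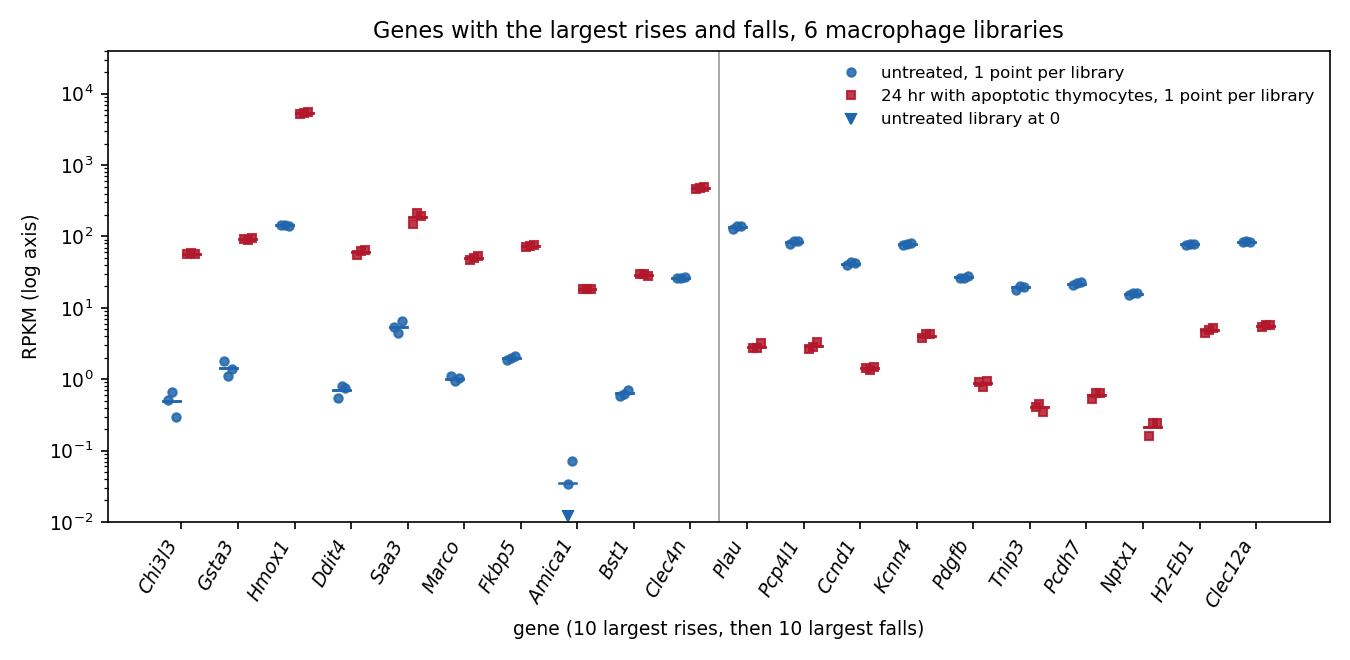
RPKM on a log axis for the 10 genes with the largest rises (left of the line) and the 10 with the largest falls (right), with 1 point per library (blue circles untreated, red squares treated) and a bar at each group's mean; a triangle at the lower edge marks the untreated library in which Amica1 was at 0. The 2 groups do not overlap in any of the 20 genes because the naming rule required this. Hmox1 reached a mean of 5322 RPKM in treated libraries.

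Genes of the pentose phosphate pathway, which makes NADPH and ribose 5-phosphate from glucose 6-phosphate, were mostly higher with apoptotic thymocytes. Of the 9 members, 6 rose, 1 fell and 2 did not pass, and the counts were the same when p was adjusted over the list alone. The genes of both NADPH-producing steps of the oxidative branch rose. Pgd (6-phosphogluconate dehydrogenase, ENSMUSG00000028961, chromosome 4, 149149991 to 149166771) rose 2.99-fold from 73.2 ± 1.17 to 219 ± 7.95 (log2 change 1.57, SE 0.0432, adjusted p = 4.73e-09). G6pdx (glucose-6-phosphate dehydrogenase, the first enzyme of the pathway, ENSMUSG00000031400, chromosome X, 74409483 to 74429194) rose 1.81-fold from 70.9 ± 0.902 to 129 ± 4.86 (log2 change 0.85, SE 0.0430, adjusted p = 2.11e-07). H6pd (chromosome 4, 149979475 to 150009023), its counterpart in the endoplasmic reticulum, rose 1.71-fold from 16.1 ± 0.824 to 27.6 ± 1.77. In the non-oxidative branch, Taldo1 (transaldolase, ENSMUSG00000025503, chromosome 7, 141392199 to 141402968) rose 2.73-fold from 267 ± 12.0 to 730 ± 35.0 (log2 change 1.45, SE 0.0546, adjusted p = 3.11e-08), and Tkt (transketolase, chromosome 14, 30548359 to 30574722) rose 1.38-fold from 60.1 ± 0.312 to 82.8 ± 4.74 (log2 change 0.45, SE 0.0486).

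The remaining members of the pathway list showed changes of small size. Rpia (ribose 5-phosphate isomerase, chromosome 6, 70765720 to 70792232) was 2.15 ± 0.0352 in untreated and 2.56 ± 0.121 in treated libraries (log2 change 0.18, adjusted p = 0.0179), and its call was lost without untreated replicate 1 (adjusted p = 0.0586), untreated replicate 3 (0.0519) or treated replicate 2 (0.0702). Rpe (ribulose-5-phosphate 3-epimerase, chromosome 1, 66700831 to 66719805) fell from 12.4 ± 0.281 to 10.7 ± 1.21 (log2 change -0.20, adjusted p = 0.0392). That call was lost with median-of-ratios scaling (log2 change -0.06, adjusted p = 0.483), with upper-quartile scaling (0.315), with no filter (0.0924) and without untreated replicate 1 (0.106), 2 (0.0952) or 3 (0.0676). Pgls (6-phosphogluconolactonase, chromosome 8, 71592176 to 71601092) was 16.8 ± 0.394 and 15.8 ± 0.912 (adjusted p = 0.162), and without treated replicate 3 it passed as lower (log2 change -0.12, adjusted p = 0.0468). Shpk (sedoheptulokinase, chromosome 11, 73199460 to 73224511) was 1.76 ± 0.109 and 1.68 ± 0.0558 (adjusted p = 0.524). The sign of Pgls and Shpk turned to positive under both scalings. As a set, the 9 genes had a mean log2 change of 0.68 relative to the median gene and passed camera (adjusted p = 0.000592), but not with an estimated correlation (adjusted p = 0.108). The fry test of a joint direction gave an adjusted p of 1.76e-05. That test, which does not set the members against other genes, passed for 20 of the 22 tested lists, 8 upward and 12 downward, and for 8 of the 9 lists that did not pass camera.

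**Figure D2:**
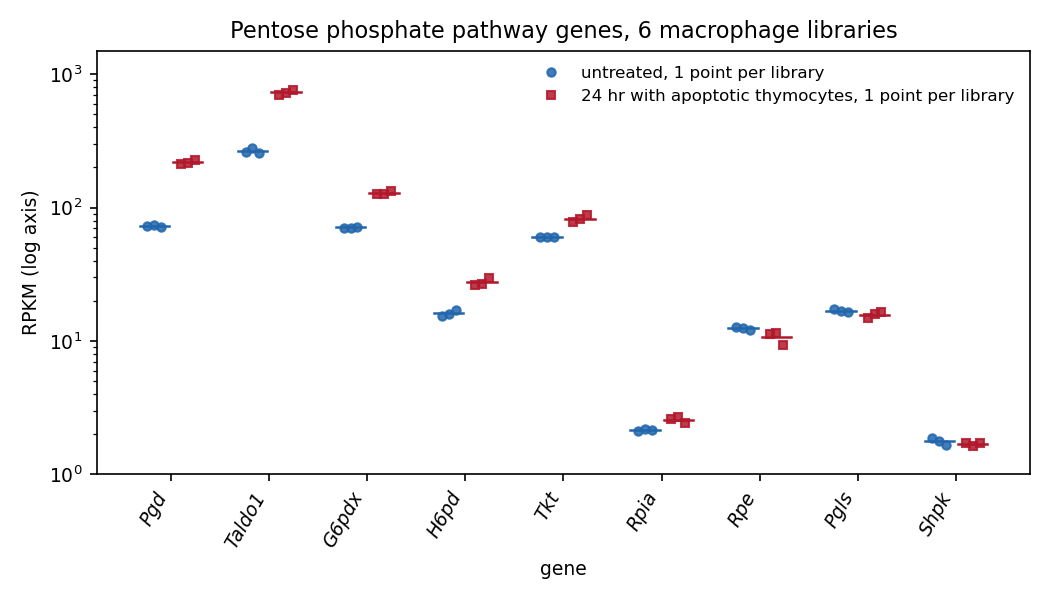
RPKM on a log axis for the 9 pentose phosphate pathway genes, with 1 point per library (blue circles untreated, red squares treated) and a bar at each group's mean. Pgd, Taldo1, G6pdx, H6pd and Tkt lie apart between the groups, with Taldo1 at 267 against 730 RPKM on average, while Pgls and Shpk overlap.

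Genes of redox defence, many of them sources or users of NADPH, rose too. Of 20 antioxidant and NADPH genes, 18 rose, 1 fell and 1 did not pass, with a mean log2 change of 1.93 relative to the median gene (camera adjusted p = 6.88e-17; adjusted p = 0.101 with an estimated correlation). Besides Hmox1, Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, rose 11.6-fold from 17.8 ± 0.635 to 206 ± 1.35, and Cat, the hydrogen peroxide-degrading catalase, rose 7.72-fold from 127 ± 1.99 to 981 ± 13.9. The fall was in Sod2 (log2 change -0.15), which did not pass with median-of-ratios scaling, and the member that did not pass was Gpx1. Of 12 tested resident and iron-recycling macrophage genes, 9 rose and 3 fell, with a mean of 1.2 relative to the median gene (camera adjusted p = 3.24e-05; adjusted p = 0.107 with an estimated correlation). Slc40a1, the iron exporter ferroportin, rose 8.87-fold from 59.4 ± 1.78 to 527 ± 13.3. Spic, a transcription factor gene of iron-recycling macrophages, rose from 0.269 ± 0.0244 to 9.91 ± 0.401. The 3 members that fell were Nr1h3, Hpgd and Cx3cr1, of which Cx3cr1 went from 6.96 to 0.0411 RPKM. Hmox1 and Nr1h3 stand in 2 lists each. Beside these rises, reads of 4 globin genes numbered 0, 1 and 0 in the untreated and 18, 23 and 18 in the treated libraries.

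Genes of cholesterol synthesis and uptake fell together. All 21 tested members were lower, by a mean log2 change of -1.39 relative to the median gene (camera adjusted p = 1.92e-09; adjusted p = 0.101 with an estimated correlation), and 21 remained lower with median-of-ratios scaling. Idi1, an isomerase of isoprenoid synthesis, fell 7.36-fold from 25.9 ± 0.555 to 3.52 ± 0.194, and Insig1, a sterol-regulated inhibitor of the pathway, fell 4.39-fold from 51.7 ± 0.929 to 11.8 ± 0.240. LXR targets, the genes of a sterol-sensing receptor, were split, with 6 of 14 higher, 6 lower and 2 not passed, and the list did not pass (camera adjusted p = 0.270). Smpdl3a rose from 235 ± 5.42 to 531 ± 17.9, whereas the lipid transfer protein gene Pltp fell from 195 ± 3.60 to 59.3 ± 4.54 and the desaturase gene Scd2 from 19.6 ± 0.243 to 7.29 ± 0.307. The mean of the LXR list was 0.06 relative to the median gene and -0.07 without that correction, and fry passed downward (adjusted p = 0.0236). Of 12 fatty acid synthesis genes, 8 fell, 2 rose and 2 did not pass (camera adjusted p = 0.141; fry downward, adjusted p = 2.70e-05). The desaturase gene Fads2 fell from 8.39 ± 0.136 to 0.676 ± 0.104, while Acss2, which makes acetyl-CoA from acetate, rose from 0.440 ± 0.0594 to 4.65 ± 0.187.

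Among 17 fatty acid oxidation and PPAR target genes, 11 rose, 4 fell and 2 did not pass, with a mean of 0.35 relative to the median gene (camera adjusted p = 0.00114; adjusted p = 0.249 with an estimated correlation). Fabp4, a fatty acid carrier, rose 3.79-fold from 168 ± 5.85 to 637 ± 16.3, and the nuclear receptor gene Ppard rose from 4.38 ± 0.295 to 7.41 ± 0.114. Pparg fell 2.64-fold from 28.3 ± 0.670 to 10.7 ± 0.144, and the other members that fell, Acadm, Hadha and Hadhb, encode enzymes of mitochondrial fatty acid oxidation. Glycolysis genes went both ways, with 8 of 17 higher, 7 lower and 2 not passed (9 higher and 7 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0827; fry adjusted p = 0.144). Pfkl, a phosphofructokinase gene at the committed step, rose 1.94-fold from 8.88 ± 0.458 to 17.3 ± 1.14 and the hexokinase gene Hk2 rose 1.61-fold from 9.05 ± 0.147 to 14.6 ± 0.245, while the lactate dehydrogenase gene Ldha fell 1.84-fold from 150 ± 4.87 to 81.7 ± 6.25. Gapdh, which has many processed pseudogenes, stood at only 31.3 RPKM in untreated and 31.0 in treated libraries, so the values of this and other genes with such copies are uncertain.

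A minority of oxidative phosphorylation genes rose, by small amounts. Of 29 members, 10 rose, 1 fell (Sdhc) and 18 did not pass, and with median-of-ratios scaling 20 rose and 1 fell. Their mean was 0.24 relative to the median gene (camera adjusted p = 0.000689; adjusted p = 0.576 with an estimated correlation; fry adjusted p = 0.109). Cox5a, a subunit of cytochrome c oxidase, rose 1.48-fold from 121 ± 1.36 to 179 ± 11.0. Sdhd rose 1.39-fold from 63.5 ± 3.17 to 88.5 ± 5.35 and Ndufa4 1.26-fold from 150 ± 5.29 to 188 ± 8.95.

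Genes of apoptotic cell recognition and uptake went both ways. Of 19 tested members, 7 rose, 11 fell and 1 did not pass, and with median-of-ratios scaling 8 rose and 9 fell. The list did not pass camera (adjusted p = 0.865) and passed fry downward (adjusted p = 0.000890). The mean and median of that list lay below the median gene, at -0.11 and -0.09, while the camera statistic pointed up. Mertk, a receptor for apoptotic cells, rose 4.33-fold from 21.9 ± 0.415 to 95 ± 4.21. Itgav, the integrin alpha-V chain that binds bridging molecules on such cells, fell 6.08-fold from 30.2 ± 0.80 to 4.96 ± 0.25, and the transglutaminase gene Tgm2 fell 3.59-fold from 75.2 ± 0.537 to 21.0 ± 1.42. Of 26 lysosome genes, 14 rose, 6 fell and 6 did not pass (14 and 7 adjusted over the list alone), and 18 rose and 5 fell with median-of-ratios scaling. Their mean was 0.29 relative to the median gene (camera adjusted p = 0.000663; adjusted p = 0.535 with an estimated correlation). Psap, the precursor of the saposins that help to degrade sphingolipids, rose 1.95-fold from 3731 ± 80.9 to 7280 ± 400, but the cathepsin gene Ctsl fell 1.73-fold from 992 ± 44.0 to 573 ± 20.8.

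Inflammatory, interferon-stimulated and antigen presentation genes fell. Of 10 tested inflammatory cytokine and NF-kB target genes, 9 fell and 1 rose (Nfkbia, which encodes an inhibitor of NF-kB), with a mean of -1.07 relative to the median gene (camera adjusted p = 0.00168; adjusted p = 0.107 with an estimated correlation). Tnf fell 11.8-fold from 19.3 ± 0.902 to 1.63 ± 0.195, the chemokine gene Cxcl2 fell 7.97-fold from 8.43 ± 0.455 to 1.06 ± 0.238, and the inflammasome sensor gene Nlrp3 fell 2.79-fold from 10.5 ± 0.238 to 3.76 ± 0.106. The other 9 members of that list, among them Il6 and Nos2, were too low to be tested. Of 23 tested interferon-stimulated genes, 22 fell and 1 did not pass, with a mean of -1.24 relative to the median gene (camera adjusted p = 3.44e-07; adjusted p = 0.215 with an estimated correlation). Oasl2 fell 6.19-fold from 26.5 ± 0.544 to 4.29 ± 0.331, Irf7, a transcription factor of the interferon response, 5.0-fold from 13.1 ± 0.140 to 2.63 ± 0.181 and Oas3 3.71-fold from 26.5 ± 0.649 to 7.14 ± 0.371. The exception was the chemokine gene Cxcl10, which passed as higher with median-of-ratios scaling. All 10 tested antigen presentation genes fell, by a mean of -1.66 relative to the median gene (camera adjusted p = 2.72e-05; adjusted p = 0.107 with an estimated correlation). Next to H2-Eb1, the MHC class II genes H2-Aa and H2-Ab1 fell 8.53-fold from 102 ± 2.12 to 12.0 ± 0.660 and 9.5-fold from 74.9 ± 1.07 to 7.89 ± 0.601.

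Alternative activation and resolution genes went both ways, with 4 of 11 tested members higher, 6 lower and 1 not passed (camera adjusted p = 0.863; fry downward, adjusted p = 3.63e-05). Its mean was 0.05 and its median -0.13 relative to the median gene. Chi3l3 rose as given above, while Egr2, a transcription factor gene, fell 22.1-fold from 7.48 ± 0.326 to 0.339 ± 0.0428 and the growth factor gene Vegfa fell 6.38-fold from 12.3 ± 0.137 to 1.93 ± 0.0737. Arg1 and Retnla, which belong to the same list, were not tested because they were below 1 RPKM.

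Cell cycle genes fell, with 20 of 21 members lower and 1 (Ccnb2) not passed, by a mean of -0.69 relative to the median gene (camera adjusted p = 4.90e-05; adjusted p = 0.108 with an estimated correlation). With median-of-ratios scaling 16 were lower and 0 higher. The DNA replication helicase genes Mcm5 and Mcm6 fell 3.88-fold from 12.6 ± 0.275 to 3.24 ± 0.0801 and 3.37-fold from 42.4 ± 2.51 to 12.6 ± 0.694, and Pcna, the replication clamp, fell 2.27-fold from 170 ± 4.90 to 75 ± 2.0. The unfolded protein and amino acid stress list was split, with 8 of 15 higher and 7 lower. It did not pass camera (adjusted p = 0.0827), though it did when genes were filtered at 5 RPKM (adjusted p = 0.0106), and it passed fry upward (adjusted p = 0.0108). The endoplasmic reticulum chaperone genes Sdf2l1, Pdia4 and Hspa5 rose 2.92-fold from 32.2 ± 0.613 to 94.1 ± 4.45, 2.38-fold from 24.0 ± 0.523 to 57.1 ± 3.22 and 2.18-fold from 127 ± 2.19 to 277 ± 12.4. The 7 members that fell were Atf4, Ddit3, Atf3, Trib3, Asns, Psat1 and Phgdh, which belong to the amino acid stress response or to amino acid synthesis, and Ddit3 did not pass with median-of-ratios scaling.

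Polyamine and arginine genes were also split, with 4 of 9 higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.471; fry downward, adjusted p = 0.00741). The mean of the polyamine list was 0.08 relative to the median gene and -0.05 without that correction. Sms, which makes spermine, fell 2.84-fold from 13 ± 0.564 to 4.56 ± 0.224 and Amd1 fell 1.5-fold from 28.8 ± 0.265 to 19.2 ± 1.16, while the mitochondrial arginase gene Arg2 rose 3.24-fold from 1.14 ± 0.146 to 3.69 ± 0.437. Of 11 tested nucleotide salvage and breakdown genes, 3 rose, 4 fell and 4 did not pass (camera adjusted p = 0.865; fry downward, adjusted p = 0.000411), and the mean and median relative to the median gene were -0.22 and 0.04. The salvage kinase genes Dck and Tk1 fell 2.38-fold from 15.4 ± 0.0793 to 6.48 ± 0.268 and from 2.63 ± 0.0310 to 0.358 ± 0.0951, and Hprt, which recycles purine bases, fell 1.6-fold from 111 ± 6.37 to 69.5 ± 0.963.

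**Figure D3:**
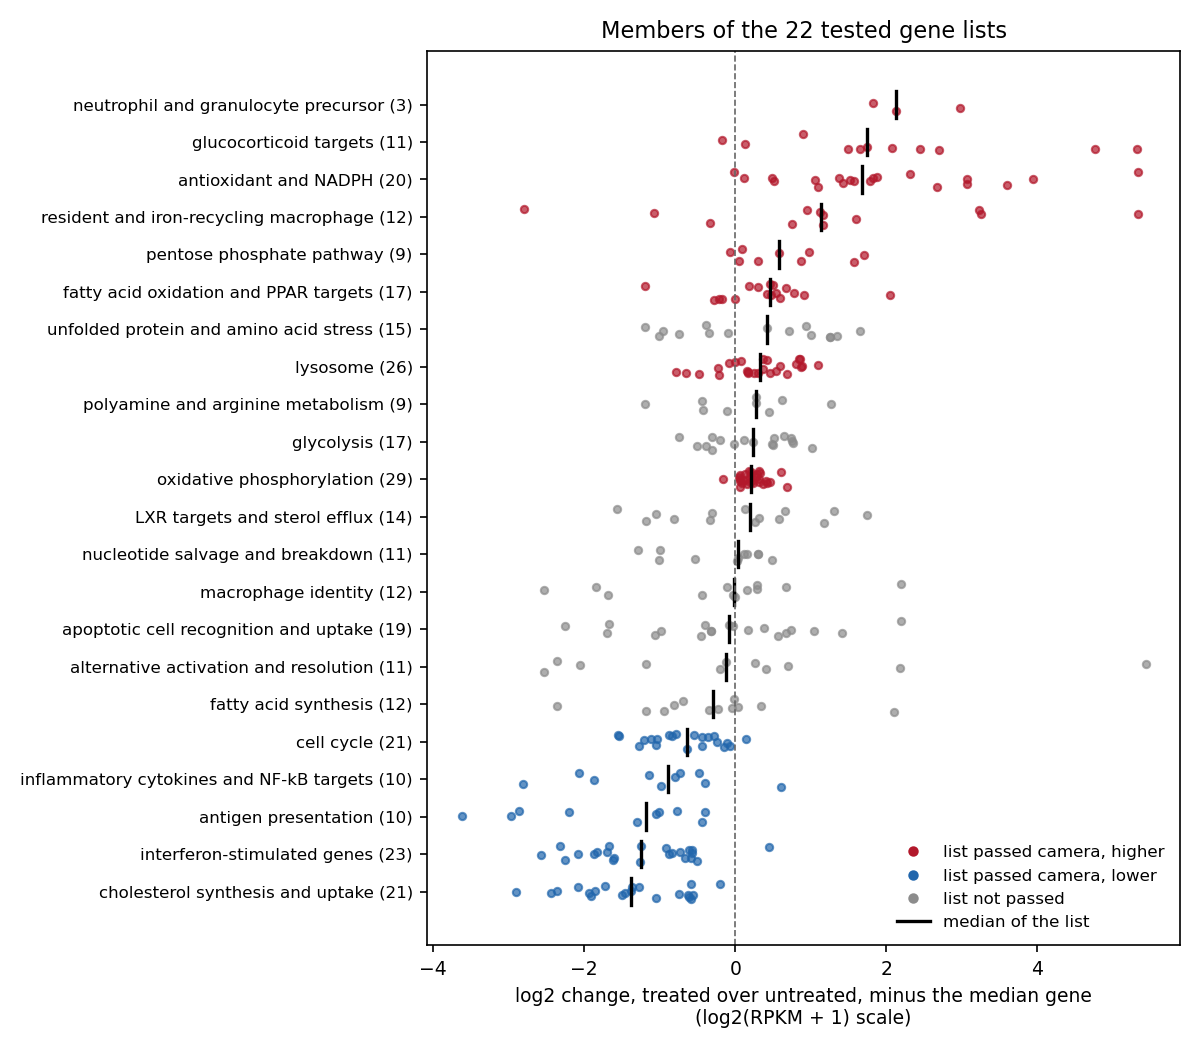
Log2 change of each tested member of the 22 tested gene lists relative to the median gene, with 1 point per gene, a black line at each list's median, the number of tested members in parentheses, and colour for the camera test with the preset correlation (red higher, blue lower, grey not passed). Medians run from -1.38 for cholesterol synthesis and uptake to 2.12 for the neutrophil list, and with an estimated correlation 0 lists passed. In the neutrophil list, S100a9 and Ngp passed the expression filter through the treated libraries alone, as did some members of other lists, such as Spic and Ddit4.

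Targets of the glucocorticoid receptor rose. Of 11 members, 9 rose, 1 fell (Errfi1) and 1 did not pass (Sgk1), with a mean of 2.10 relative to the median gene (camera adjusted p = 9.84e-09; adjusted p = 0.101 with an estimated correlation). With Fkbp5 and Ddit4, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose 5.24-fold from 14.8 ± 1.34 to 77.4 ± 2.99. Sgk1 passed as higher with median-of-ratios scaling. The added thymocytes had been killed with dexamethasone, and the 6 libraries hold no group given dexamethasone alone.

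Macrophage identity genes went both ways, with 4 of 12 higher, 7 lower and 1 not passed (camera adjusted p = 0.865; fry downward, adjusted p = 0.000404). Fcgr1, a high-affinity Fc receptor, fell 7.09-fold from 52.7 ± 2.54 to 7.43 ± 0.401 and Itgam, the CD11b integrin, 3.61-fold from 119 ± 1.74 to 33.1 ± 0.695. Mertk, which also stands in this list, rose 4.33-fold as given above. Lyz2, the lysozyme gene of myeloid cells, rose 1.45-fold from 13388 ± 408 to 19419 ± 1128, a call that was lost with no filter (adjusted p = 0.132). Tyrobp was 1693 ± 52.3 and 1894 ± 120 (adjusted p = 0.0484) and Cd68 was 1274 ± 26.9 and 1144 ± 35.0 (adjusted p = 0.0227). The Cd68 call was lost under both scalings (0.922 and 0.484), with no filter (0.0873) and without untreated replicate 1 (0.0831), untreated replicate 3 (0.108) or treated replicate 2 (0.0847). That of Tyrobp was lost with no filter (0.180), with the smaller pseudocount (0.050) and without untreated replicate 1 (0.167), 2 (0.0637) or 3 (0.137) or treated replicate 2 (0.158) or 3 (0.109).

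Most thymocyte, T cell and B cell markers were too low to be tested. Of 26 thymocyte and T cell markers, 1 was high enough to be tested, Cd4, and it fell from 4.32 ± 0.165 to 2.14 ± 0.155 RPKM. Reads over that list numbered 1447 in untreated and 785 in treated libraries, and in treated libraries Satb1 stood at 0.0863 ± 0.0105 and Trbc2 at 0.0815 ± 0.141 RPKM. Of 8 B cell markers, Ighm was tested and fell from 2.25 ± 0.151 to 0.678 ± 0.188, and Cd79b and Cd79a stood at 0.0963 and 0.0575 RPKM in treated libraries. Neutrophil and granulocyte precursor markers were higher. S100a9 rose from 0.726 ± 0.0647 to 11.5 ± 0.823, S100a8 from 5.86 ± 0.291 to 26.3 ± 1.30 and Ngp from 0.181 ± 0.111 to 2.81 ± 0.122, and these 3 tested members of 10 passed as a list (camera adjusted p = 0.000115; adjusted p = 0.107 with an estimated correlation). S100a9 and Ngp were below 1 RPKM in every untreated library and passed the expression filter through the treated libraries alone. The list test is therefore biased toward a rise. Other lists hold such members too. Spic in the iron-recycling list, Ddit4 in the glucocorticoid list, Chi3l3 and Acss2 passed the filter through the treated libraries alone. Fads2, Egr2 and Tk1 passed through the untreated libraries alone. The tests of their lists lean toward the direction of these members, by an amount that was not tested. Reads over the 10 markers numbered 206 in untreated and 1543 in treated libraries.

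The remaining cell type lists had 0 tested members. Among dendritic cell markers, Ccr7 had the highest treated mean, 0.115 RPKM, followed by Zbtb46 and Clec9a at 0.0162 and 0.0130. The fibroblast markers Dcn, Col1a1 and Col1a2 stood at 0.568, 0.496 and 0.385 RPKM in treated and at 1.11, 0.653 and 0.531 in untreated libraries. Erythroid markers had 1 read in untreated and 61 in treated libraries, with Hba-a2, Hba-a1 and Hbb-b1 at 0.704, 0.233 and 0.161 RPKM in treated libraries. The mast cell and basophil markers Mcpt8, Gata2 and Cpa3 stood at 0.0808, 0.0210 and 0 RPKM in treated libraries, with 26 reads over the list in untreated and 10 in treated libraries.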

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

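Apart from the gene set kept in the fits that leave out a library, all alternatives were fixed before the data were examined. Of the 1149 comparisons with an alternative of the 89 tested genes picked by the naming rule, 1121 kept direction and call, 23 lost the call, 1 gained it and 4 changed sign. Most of these genes were picked for a large change or a small p, so this share does not carry over to all calls. Of the 307 comparisons of the 22 lists, 286 kept both, 13 lost the call, 1 gained it and 7 changed sign. The counts of changed genes moved by over 1.5 times in 2 ways. With median-of-ratios scaling 3064 genes were higher and 3023 lower, because that scaling centres the median gene. With a log2 change over 1 required in addition, 824 genes were changed, 250 higher and 574 lower, because the threshold leaves out small changes. Under the other settings the total lay between 4713 (filter at 5 RPKM, which tests fewer genes) and 7299 (no filter).

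Leaving out 1 library gave 5675 to 6755 changed genes, 1630 to 2048 higher and 4045 to 4712 lower, with a mean of 0.66 to 0.69 for the pentose phosphate pathway list. That list kept its call under every setting except the estimated correlation (mean 0.68, adjusted p = 0.108, against 0.000318 to 0.00198 elsewhere), and all 13 list calls were lost there. The inflammatory list lost its call although its estimated correlation was -0.0456 (unadjusted camera p = 0.000991 preset and 0.0263 estimated). Correlation among members therefore cannot account for every loss. The fewer degrees of freedom of that setting raise p for every list, whatever its correlation. How much each contributed was not tested. Limma-voom on the recovered reads called 6612 genes, 1887 higher and 4725 lower, and 6474 calls were shared with the RPKM fit in the same direction.

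Sign changes were limited to results that had not passed. Pgls and Shpk became positive with median-of-ratios scaling (0.0524 and 0.0506) and with upper-quartile scaling (0.0209 and 0.0294), because both scalings raise the treated libraries. The cause of the following changes was not tested. The mean of the alternative activation list became -0.0232 with limma-voom, -0.13 with the filter at 5 RPKM and -0.0204 with a pseudocount of 0.1. That of LXR targets became -0.0434 with no filter and -0.0266 with the filter at 5 RPKM, and that of polyamine genes -0.0274 and -0.0940.

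With the replicate number as a block, 6531 genes were changed, 1904 higher and 4627 lower. Deviations of same-numbered libraries from their group means correlated at 0.20, -0.03 and -0.16 across genes. Untreated replicate 2 correlated best with treated replicate 3 (0.33). These values show no common pairing by number, but with 3 libraries per group they cannot exclude a shared mouse or day. The planned Wald test and scaling by trimmed means were kept for deposited counts and not run, and limma-voom was the test run on the recovered reads. Depth limits what can be said of low genes. On a gene of 2 kb, 3 reads were worth 0.0578 to 0.0777 RPKM.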

Other observations

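The tests of symbol families, of abundant transcripts, of glucocorticoid targets, of thymocyte RNA and of globin reads were chosen after the results were seen, and the count of other splits before. Tested genes were grouped by the stem of their symbol into 237 families of at least 6 members, to look for gene groups outside the fixed lists. In camera with the preset correlation, 11 families passed, and with an estimated correlation 0 did (adjusted p = 0.955 for each of the 11). Sec genes, which mostly build the translocon and the coats of secretory vesicles, had 16 of 22 members higher and 2 lower, with a median of 0.39 relative to the median gene (adjusted p = 7.65e-05). With median-of-ratios scaling 18 of them were higher and 0 lower. Among proteasome genes, Psmd had 9 of 14 higher and 2 lower (adjusted p = 0.0211), Psma 5 of 7 higher (adjusted p = 0.0461) and Psmc 4 of 6 higher (adjusted p = 0.0461), with medians of 0.31, 0.37 and 0.32, whereas Psmb, with 5 of 10 higher and 2 lower, did not pass (adjusted p = 0.490).

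Families that fell included more than the class II genes. The H2- stem holds MHC class I genes among others and overlaps the fixed antigen presentation list, as with H2-Aa, H2-Ab1 and H2-Eb1. Of 20 H2- genes, 18 were lower and 1 higher, with a median of -0.91 relative to the median gene (adjusted p = 0.00102). Under both scalings 17 were lower and 2 higher. These genes share sequence, so single values are uncertain. All 7 tested Rgs genes, regulators of G protein signalling, were lower, with a median of -0.51 (adjusted p = 0.0461), and 5 were lower under both scalings. Mcm and Oas genes also passed as lower and overlap the fixed cell cycle and interferon lists. The Ndufb, Mrpl and Atp stems passed as higher, with 6 of 10, 11 of 47 and 20 of 52 higher and 0, 4 and 12 lower. Over all 10173 tested genes 1915 were higher and 4679 lower, so Mrpl differed more by few falls than by many rises. The Atp stem joins mitochondrial Atp5 genes with vacuolar Atp6v and other pump genes. The Ndufa, Ndufs and Ndufaf stems, related to Ndufb, and Mrps, related to Mrpl, did not pass. Nor did mt-Nd, with 0 of 7 higher and 6 lower.

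The count of 6594 changed genes can be set beside other splits of the 6 libraries. Of the 10 splits into 3 and 3, 1, the real split, gave as many, and the highest of the others gave 0. So few splits cannot give a share under 0.05.

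More genes were lower than higher. A candidate explanation is that a few abundant transcripts took a larger share of the treated libraries and pushed down the RPKM of the rest, as Fth1 went from 1.27% to 2.56% and Hmox1 from 0.0341% to 1.24% of gene reads. With the reads of the 20 most abundant genes taken out of the denominator, the median log2 change of the other genes went from -0.131 to -0.0438. That lies inside a bound of 0.05, but the bound was set after the results were seen, and part of the shift remained. A rise of the other genes is fixed by the larger share of these 20 genes in treated libraries, so it does not decide the cause. The near-equal split under median-of-ratios scaling is fixed by its centring and is no evidence. Upper-quartile scaling, which likewise aligns the libraries, left a median gene at -0.0323, with 2762 genes higher and 3297 lower. A response to the apoptotic cells in which more genes fall than rise stays open as an untested biological explanation.

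Glucocorticoid targets rose, with 9 of 11 higher and a median of 1.74 relative to the median gene. RNA of the added thymocytes as the source is argued against by thymocyte and T cell markers, whose largest rise was 0.0815 RPKM, while Fkbp5 rose to 73.2 and Ddit4 to 61.3 RPKM. Dexamethasone carried over with the thymocytes may have acted on the macrophages, but the rise is the pattern itself and does not test this. Carry-over and a response to the uptake of apoptotic cells cannot be told apart, since the 6 libraries hold no macrophages given dexamethasone alone and none given thymocytes killed in another way. The same controls would be needed for the lower inflammatory genes and for every other difference between the groups. Among these are the pentose phosphate pathway, antioxidant and iron-recycling genes.

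Hmox1, Slc40a1, Spic and Blvrb, which belong to the resident and iron-recycling macrophage list and were picked after their values were seen, rose. Of the 12 tested members of that list 9 rose and 3 fell, and the list did not pass with an estimated correlation (adjusted p = 0.107). Red cell material in the thymocyte preparation is a candidate source of heme. Globin reads numbered 1 in untreated and 59 in treated libraries, a ratio per mapped read of 54.1 with an exact binomial 95% interval of 9.34 to 2173.5, so globin reads were more frequent in treated libraries. The amount of heme cannot be read from 59 reads. Globin genes lie in pairs of near-identical copies, so the reads of all 4 were summed. A response to oxidants or to the uptake of apoptotic cells, with 18 of 20 antioxidant and NADPH genes higher, stays open and was not tested apart from it.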
